A study of Mus musculus with 8 samples.

How the data were processed

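The 8 libraries hold sorted and fixed M-MDSC from mouse spleen, 2 from naive mice, 3 from mice on day 21 after LLC tumour implantation and 3 from mice on day 14 of LCMV infection, per the labels. The labels conflict on the assay. The series design speaks of a kit for fixed tissue and of total RNA sequencing, while the extraction protocol of the samples names Direct-zol columns, DNase-treated total RNA and the QuantSeq 3′ mRNA kit, and calls the cells macrophages. Which of these was used could not be settled from the counts and is left open, and so are the read layout and whether a gene's count depends on its length. Replicate numbers are the G numbers in the sample titles, whose meaning is not stated.

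The deposited table holds estimated counts per gene, not normalised across samples, with Ensembl gene identifiers. Per the submitters' processing notes, HTSeq 0.9.1 and genome build mm10 were used. HTSeq counts whole reads, but 0% of the deposited values above 0 were whole at a tolerance of 1e-06, so how the estimated counts arose, and the aligner and annotation release, are not given in the sources used here. The table has 53465 genes, of which 53274 matched GENCODE mouse release M21 (GRCm38) and 191 did not, and 32257 were at 0 in every library. All 8 libraries were used. Column totals ranged from 25513447 to 43238729 estimated counts, but counts on nuclear protein-coding genes, called coding genes here, ranged from 318745 in LCMV replicate 1 to 5797508 in naive replicate 2. A count of 0 in every library of a group allows up to 3 counts over the group, which is 0.0153 CPM in naive, 0.0346 in LLC and 0.0499 in LCMV, and folds against such a group are bounds computed at that floor. A gene with 1 to 3 counts in a group is given as the ratio of pooled levels with an exact 95% Poisson interval. No pair of libraries of a group agreed within sampling noise (chi-square per degree of freedom from 15.4 to 88.6 over genes with a pair count of at least 10), and each was kept as a separate library. Noise from amplification would also give such values, so technical duplicates cannot be excluded by them.

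Counts were rounded to whole numbers and fitted with edgeR 4.0.16 in R 4.3.3 with the package data.table, version 1.17.8, for reading. The fit used TMM normalisation, filterByExpr by group with a minimum count of 10 and a minimum total of 15, and 1 quasi-likelihood fit of all 8 libraries with 3 group means, so that the naive group of 2 shared the estimate of spread. This kept 14356 genes, 11233 of them nuclear protein-coding. The 3 comparisons were LLC against LCMV, which the series design names, LLC against naive, and LCMV against naive, with log2 fold changes coded as the first minus the second group. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The standard error of a log2 fold change was computed as its absolute value divided by the square root of the F statistic. Levels are TMM-scaled CPM, and mean log2 CPM used a prior count of 2. The common dispersion was 1.04.

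The samples, groups, comparisons, tests, gene lists, named genes and most alternatives were chosen before the data were examined. The 33 lists cover the type I interferon response, the interferon-gamma response, MHC class I presentation, MHC class II presentation, MDSC suppression genes, classical monocyte identity, non-classical monocyte identity, monocyte and granulocyte progenitors, neutrophils, red pulp and other macrophages, dendritic cells, B cells, plasma cells, T cells, NK and cytotoxic cells, erythroid cells, megakaryocytes and platelets, basophils with eosinophils and mast cells, stroma with endothelium and carcinoma, S phase, G2 and M phase, replication-dependent histones, the unfolded protein response, hypoxia and glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cytoplasmic ribosomal proteins, the NF-kB inflammatory response, immediate early and handling stress genes, cholesterol synthesis and uptake, fatty acid uptake with storage and oxidation, complement and Fc receptors, and autophagy and lysosome. Lists with at least 5 tested genes were tested with camera of limma 3.58.1 at its preset correlation of 0.01, adjusted over the lists of a comparison. Camera asks whether a list ranks away from the other genes. The call was repeated with a correlation estimated per list, and with fry, a self-contained rotation test of whether a list's genes move on balance 1 way, which does not compare them with other genes.

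Genes were named by a rule with 3 parts. Part a took up to 10 genes each way with the largest fold among those past the threshold over all genes, with groups that do not overlap and at least 5 CPM in the higher group, and it named 0 genes. Part b took up to 4 genes of each list with the smallest p among those at an adjusted p under 0.05, or the 2 with the highest mean CPM where none passed. Because none passed over all genes, the adjusted p of part b was read over the list alone, a reading chosen after seeing the data. Part c named 25 fixed genes whatever their p. Irf7, Mpo, Gfi1 and the other genes outside these parts were singled out after their values were seen.

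The pipeline was tested on simulated data with 200 changed genes added to unchanged groups of 3 and 3. With the spread estimated per gene from these libraries, edgeR found 0%, 0%, 0% and 6% of genes changed 2-, 4-, 8- and 16-fold and 0% of unchanged genes. DESeq2 1.42.0 found 2%, 14%, 42.9% and 68% and called 0.674% of unchanged genes. Those rates were over 49 or 50 genes at each fold and 14118 unchanged genes. DESeq2 therefore called more unchanged genes than right ones among the 200 changed genes. With a dispersion of 0.1 edgeR found 22%, 88%, 100% and 100%. A list given a simulated change was called by camera (adjusted p 2.34e-11), with 0 of the other lists called. Genes were drawn independently of each other there. In the real libraries the estimated correlation was 0.429 for the type I interferon list in LLC against LCMV. The simulation therefore does not show how often camera at its preset correlation calls unchanged lists in these data.

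Alternatives replaced TMM by DESeq2 size factors or total library size, and replaced the test by DESeq2 or limma-voom. They kept every gene with at least 1 count or only those with a mean of at least 5 CPM. Mitochondrial and haemoglobin genes and RNA genes such as Rn7s1 and Rn7s2 were taken out before normalisation. That removal left in Gm26917 and Gm42418, which held most counts in every library. Further alternatives required a 2-fold change, fitted only the 2 groups compared, added the replicate number as a block, and left out each library in turn. After seeing LCMV replicate 1, limma-voom with sample quality weights, fits without that library and camera on weighted values were added. Equal depth was simulated with 20 thinning draws, and shared controls with 20 simulations.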

Results

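Gene expression was measured in monocytic myeloid-derived suppressor cells (M-MDSC), immature cells of the monocyte lineage that can restrain T cells, sorted from mouse spleen and fixed. The 8 libraries came from C57BL/6 mice in 3 groups. Naive mice gave 2 libraries, numbered replicates 2 and 3. Mice with an LLC tumour, the abbreviation usually read as Lewis lung carcinoma, gave 3 libraries on day 21. Mice infected with lymphocytic choriomeningitis virus (LCMV) gave 3 libraries on day 14. The labels do not say that replicates were separate animals, so every p-value measures only the spread between these samples, which may be technical. Total estimated counts were 30979476 and 25751411 in naive replicates 2 and 3. They were 43238729, 30496075 and 38877773 in LLC replicates 1 to 3. They were 25513447, 29967891 and 36216432 in LCMV replicates 1 to 3.

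Most counts did not fall on protein-coding genes. Coding genes here mean nuclear ones, without the 13 mitochondrially encoded genes, unless stated. Gm26917, a long non-coding RNA gene at chromosome 17 from 39843013 to 39846341 (GRCm38), lies beside the ribosomal RNA gene CT010467.1, and its reads cannot be told from ribosomal RNA by a gene table. It took 55.1% ± 5.81 (SD, n = 2) of the counts in naive, 74.4% ± 4.08 (n = 3) in LLC and 66.8% ± 4.26 (n = 3) in LCMV libraries. Gm42418, which overlaps the same ribosomal RNA gene, took 8.19% ± 2.09, 11.1% ± 4.53 and 18.1% ± 2.62. Nuclear protein-coding genes held 20.5% ± 2.53 of the counts in naive, 4.25% ± 1.53 in LLC and 3.36% ± 2.55 in LCMV libraries, and mitochondrially encoded coding genes a further 2.70% ± 2.54, 3.18% ± 2.00 and 1.32% ± 0.546, so that naive libraries were the deepest on nuclear coding genes. Replicate 1 of the LCMV group stood apart, with 318745 coding counts over 2731 coding genes, where the other libraries detected 9360 to 12809 coding genes. Its correlation with the other libraries across genes was 0.344 to 0.468. On the first principal component, which held 63.6% of the variance, it lay at 452, where the other libraries lay from -99.8 to 4.20.

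**Figure D1:**
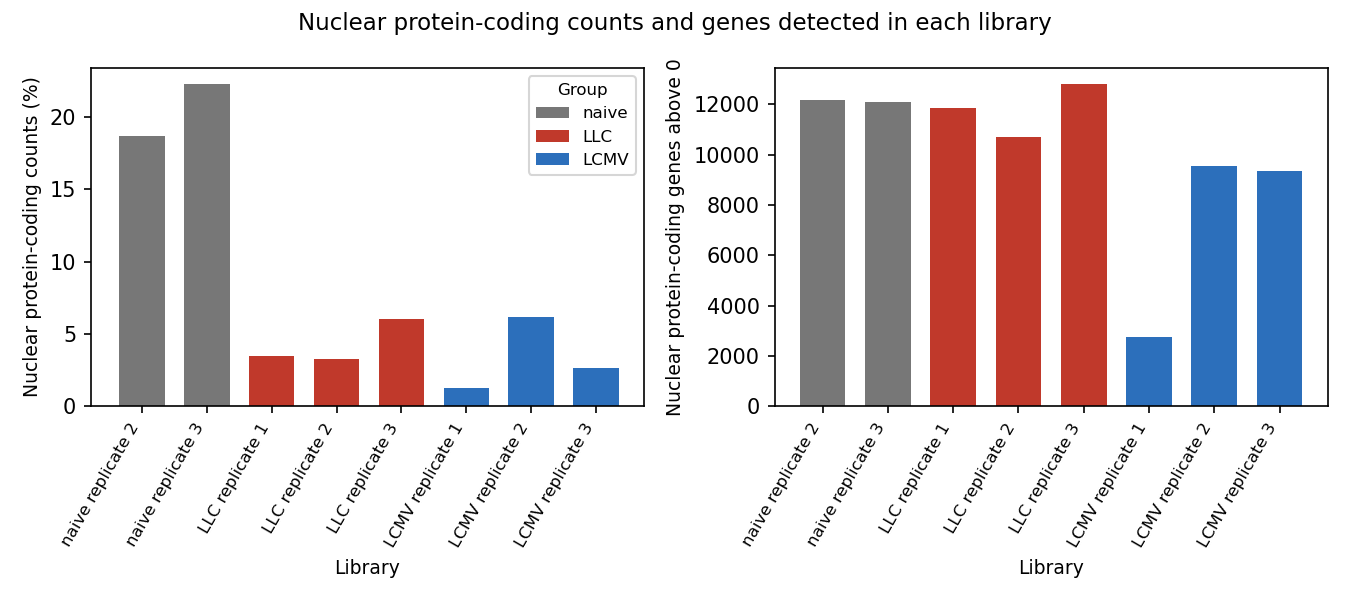
Bars show, for each of the 8 libraries, the counts on nuclear protein-coding genes as a percent of the library (1 panel) and the number of nuclear protein-coding genes above 0 (other panel), coloured by group. The naive libraries hold 18.7% and 22.3% nuclear coding counts, all LLC and LCMV libraries hold 1.25% to 6.19%, and LCMV replicate 1 detects 2731 nuclear coding genes.

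In the tests of single genes over the 14356 genes kept, edgeR called 0 genes at an adjusted p under 0.05 in each of the 3 comparisons. At an unadjusted p under 0.05 there were 1982 genes between LLC and LCMV, 280 between LLC and naive and 1982 between LCMV and naive, where 717.8 were expected by chance in each. DESeq2 called 841, 19 and 413 genes in the same order, and limma-voom 0, 1 and 31. In the simulated data with this spread DESeq2 called more unchanged genes than right ones, so its counts may hold many false calls. Without LCMV replicate 1, edgeR still called 0 in each comparison, with 2545, 1162 and 2585 genes at an unadjusted p under 0.05. The median standard error of a log2 fold change was 1.40, 1.51 and 1.54. Groups did not overlap for 3192 genes between LLC and LCMV, which is 22.2% where chance gives 10%. They did not overlap for 4991 genes (34.8%) between LLC and naive and for 5393 genes (37.6%) between LCMV and naive, where chance gives 20%. The gene groups below are therefore lists fixed in advance, tested as sets with camera and gene by gene with edgeR p-values adjusted over the list alone. Over all genes, 0 members of any list passed in edgeR. Levels are mean ± SD of CPM, which are counts scaled to the TMM-adjusted library size, with n = 3 for LLC and LCMV and n = 2 for naive, and intervals and floors cover counting error only. Thinned to equal coding depth, the LCMV libraries detected 2730 to 9115 coding genes and the LLC and naive libraries 10098 to 11156. Bounds for genes at 0 in LCMV do not allow for this lower detection.

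The median log2 fold change of all tested genes was 0.61 for LLC against LCMV, -0.07 for LLC against naive and -0.66 for LCMV against naive. With DESeq2 size factors it was 0.71, -0.05 and -0.75, and with total library size alone 0.68, -2.23 and -2.89. List medians are therefore also given relative to the median of all genes, and no list called by camera changed its relative direction between the 3 scalings in the comparison where it was called. Camera itself compares a list with the other genes, so its direction is a relative one.

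The series names LLC against LCMV as its comparison, which asks how M-MDSC of tumour-bearing mice differ from those of infected mice. Interferon-stimulated genes, the antiviral programme that interferons switch on, were lower in LLC. Of 39 tested genes of the type I interferon list, 35 had a lower estimate in LLC, 2 fell when adjusted over the list alone, 0 rose and the rest did not pass. Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009), which binds viral RNA, was at 0.155 ± 0.125 CPM in LLC, 5.90 ± 2.62 in LCMV and 0.711 ± 0.00126 in naive, a log2 fold change of -5.26 (SE 1.30, adjusted p over the list alone 0.0433). Ifi204 (ENSMUSG00000073489, chromosome 1, 173747293 to 173766943), a nucleic acid sensor from a family of close paralogs whose reads may be shared, was at 7.44 ± 1.63 CPM in LLC, 53.5 ± 15.6 in LCMV and 34.4 ± 3.09 in naive, a log2 fold change of -2.85 (SE 0.74, adjusted p over the list alone 0.0433). Irf7, a master regulator of the programme, had -2.56 (SE 0.81) and Isg15, a ubiquitin-like modifier, -5.69 (SE 1.85), and neither passed, with adjusted p of 0.0712 over the list alone.

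As a set the type I interferon list had a median log2 fold change of -1.75, or -2.36 relative to all genes, and camera gave an adjusted p of 8.08e-15. The call was lost when the correlation between genes was estimated, with adjusted p = 0.840 with an estimated correlation. Without LCMV replicate 1, 27 of the 39 genes fell adjusted over the list alone, and the set passed with adjusted p = 0.00538 with an estimated correlation. The single-gene calls on Ifit1 and Ifi204 held without LCMV replicate 1 but ended when any 1 other library of the 2 groups was left out. The adjusted p of both was 0.296 without LLC replicate 1, 0.149 without LLC replicate 2 and 0.267 without LLC replicate 3. For Ifit1 and Ifi204 in turn it was 0.0787 and 0.0851 without LCMV replicate 2 and 0.0654 and 0.105 without LCMV replicate 3. Their log2 fold changes stayed between -5.96 and -4.79 for Ifit1 and between -3.01 and -2.59 for Ifi204. The summed level of the list was 211 CPM in LCMV replicate 1 against 608 and 726 CPM in LCMV replicates 2 and 3, 181 to 185 CPM in the LLC libraries and 335 and 385 CPM in the naive libraries.

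The interferon-gamma list, which holds guanylate-binding proteins, immunity-related GTPases and chemokines, was lower in LLC as well. Of 37 tested genes 31 had a lower estimate, 4 fell adjusted over the list alone, 0 rose and the rest did not pass. Cd274 (ENSMUSG00000016496, chromosome 19, 29367455 to 29388095), which encodes the T cell inhibitory ligand PD-L1, was at 3.85 ± 4.90 CPM in LLC, 94.4 ± 80.7 in LCMV and 8.98 ± 3.30 in naive, a log2 fold change of -4.62 (SE 1.16, adjusted p over the list alone 0.0208). Iigp1, an immunity-related GTPase with close paralogs, was at 0 in all 3 LLC libraries and at 5.50 ± 3.61 CPM in LCMV, which is at least 159-fold lower with the floor set at 3 counts over the group (adjusted p over the list alone 0.0208). Gbp6, one of several near-identical guanylate-binding protein genes, had a log2 fold change of -5.80 (SE 1.39, adjusted p 0.0208), and Gm4951, an interferon-inducible GTPase gene, had 2 counts in LLC and 253 in LCMV, a ratio of 183 in favour of LCMV with a counting interval from 50.0 to 1516 (adjusted p 0.0487). The chemokine gene Cxcl9 had 1 count in LLC and 25 in LCMV, a ratio of 36.1 (counting interval 5.91 to 1481), and did not pass among the fixed genes, at an adjusted p of 0.0519.

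The median of the interferon-gamma list was -1.57, or -2.18 relative to all genes. Camera gave it an adjusted p of 4.86e-12, which became adjusted p = 0.840 with an estimated correlation. Without LCMV replicate 1, 18 of the 37 genes fell adjusted over the list alone, and the set passed with adjusted p = 0.0423 with an estimated correlation. Cd274 was at 187 CPM in LCMV replicate 1 and at 54.2 and 41.6 CPM in LCMV replicates 2 and 3. Its log2 fold change was -3.66 without LCMV replicate 1 and -6.52 without LLC replicate 2, and in this list its call ended without LLC replicate 1 (adjusted p 0.135) or LLC replicate 3 (0.126). The calls on Iigp1 and Gbp6 ended without LLC replicate 1 (adjusted p 0.135), LLC replicate 2 (0.0706) or LLC replicate 3 (0.117), and the fitted log2 fold change of Gbp6 was -7.07 without LLC replicate 3, which leaves few counts in LLC. The call on Gm4951 ended without LLC replicate 1 (0.275), LLC replicate 2 (0.222), LLC replicate 3 (0.162), LCMV replicate 2 (0.0913) or LCMV replicate 3 (0.0709), and without LLC replicate 3 its LLC group was at 0. Its fitted log2 fold change was -7.07 and moved to -5.87 without LCMV replicate 2.

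Antigen presentation genes were lower in LLC than in LCMV relative to all genes. In the MHC class I list, 14 of 16 genes had a lower estimate and 1 fell adjusted over the list alone. That gene was H2-Q7, a non-classical class I gene with near-identical neighbours, at 6.75 ± 2.00 CPM in LLC, 54.1 ± 18.9 in LCMV and 15.9 ± 5.50 in naive (log2 fold change -3.00, SE 0.79, adjusted p over the list alone 0.0361). The class I median was -0.69, or -1.30 relative to all genes. Its camera adjusted p was 1.84e-04, with adjusted p = 0.887 with an estimated correlation. The call on H2-Q7 ended without LLC replicate 1 (0.276), LLC replicate 3 (0.196), LCMV replicate 2 (0.0858) or LCMV replicate 3 (0.0929). In the MHC class II list, 11 of 14 genes had a lower estimate and 0 passed over the list alone, among them Cd74, the invariant chain, with -0.90 (SE 1.04) and the protease gene Ctss with -1.08 (SE 0.87). The class II median was -0.73, or -1.33 relative to all genes, with a camera adjusted p of 0.0440 and adjusted p = 0.980 with an estimated correlation. That call ended without LLC replicate 1 (0.0840), LLC replicate 3 (0.106) or LCMV replicate 2 (0.628), and with the replicate number as a block (0.0798).

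Camera also ranked the T cell and red pulp macrophage lists lower in LLC relative to all genes, at its preset correlation alone. The T cell list was lower in LLC, with 6 of 8 tested genes lower and 0 passing over the list alone. It had a median of -1.75, or -2.35 relative to all genes, a camera adjusted p of 0.0390 and adjusted p = 0.840 with an estimated correlation. The levels were low, with 2.29 ± 0.601 CPM summed over the 8 genes in LLC, 5.14 ± 0.282 in LCMV and 3.03 ± 1.44 in naive, and Cd8b1, a chain of the CD8 coreceptor, at 0.556 ± 0.264 CPM in LLC and 2.02 ± 2.77 in LCMV. The T cell call ended without LLC replicate 2 (0.0921), LCMV replicate 1 (0.136), LCMV replicate 2 (0.326) or LCMV replicate 3 (0.265), and with the replicate number as a block (0.0706). The red pulp macrophage list had 8 of 15 genes lower and 6 higher in LLC, with a median of -0.42, a mean of -0.00 and a relative median of -1.03. Its camera adjusted p was 0.0479, with adjusted p = 0.840 with an estimated correlation, and the call ended without LLC replicate 1 (0.0989), LLC replicate 3 (0.106), LCMV replicate 2 (0.0503) or LCMV replicate 3 (0.110). The block also ended it (0.0885). Adgre1, which encodes the macrophage antigen F4/80, had 0.44 (SE 1.26) and the metal transporter gene Slc11a1 0.14 (SE 1.28).

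Cell cycle genes mostly had higher estimates in LLC than in LCMV. In the S phase list, 32 of 38 genes had a higher estimate, 2 rose adjusted over the list alone and 0 fell. Cdc45 (chromosome 16, 18780447 to 18811987), part of the replicative helicase, was at 2.47 ± 0.188 CPM in LLC and at 0 in all 3 LCMV libraries, at least 49.6-fold higher. Chaf1b, a histone chaperone subunit, was at least 39.3-fold higher, and both had an adjusted p of 0.0306 over the list alone. The S phase median was 1.15, or 0.55 relative to all genes, with a camera adjusted p of 0.0209 and adjusted p = 0.980 with an estimated correlation. In the G2 and M phase list, 38 of 41 genes had a higher estimate and 0 passed over the list alone, with Mki67, the proliferation marker Ki-67, at 52.0 ± 30.3 CPM in LLC and 21.7 ± 19.6 in LCMV. The G2 and M median was 1.23, or 0.63 relative to all genes, with a camera adjusted p of 0.0319 and adjusted p = 0.980 with an estimated correlation. The S phase call ended without LLC replicate 1 (0.0840) or LCMV replicate 3 (0.0888), and the G2 and M call without LLC replicate 1 (0.0840), LLC replicate 3 (0.106) or LCMV replicate 3 (0.393). With the replicate number as a block both calls ended, at 0.0706 for S phase and 0.0798 for G2 and M. Without LCMV replicate 1 the medians were 0.64 and 0.68, where that of all genes was 0.22. Camera kept both calls there (0.0332 and 0.0217), but not with an estimated correlation (adjusted p 0.445 and 0.691). By mean log2 CPM of G2 and M genes the groups overlapped, with LLC replicate 2 at 1.44 and LCMV replicate 2 at 1.53. The calls on Cdc45 and Chaf1b ended without LLC replicate 1 (0.119), LLC replicate 2 (0.0908) or LLC replicate 3 (0.0969).

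Single genes passed over the list alone in lists that camera did not call. Flt3 (chromosome 5, 147330741 to 147400489), a growth factor receptor of early progenitors and dendritic cells, was at 2.25 ± 0.989 CPM in LLC, 2.75 ± 0.0448 in naive and 0 in all 3 LCMV libraries, at least 45.0-fold higher in LLC than in LCMV (adjusted p over the list alone 0.0153). It was the 1 gene that rose in the progenitor list and in the dendritic cell list, and the calls ended without LLC replicate 2 (0.0698 in both) or LLC replicate 3 (0.0865 and 0.0916). Fcgr2b (chromosome 1, 170958617 to 170976547), the inhibitory Fc receptor, fell in LLC with 28.5 ± 18.9 CPM against 364 ± 353 in LCMV and 44.4 ± 4.56 in naive (log2 fold change -3.67, SE 0.88, adjusted p 0.0165). It was at 771 CPM in LCMV replicate 1 and at 159 and 163 CPM in LCMV replicates 2 and 3. Its log2 fold change was -2.50 without LCMV replicate 1, and its call ended without LLC replicate 1 (0.112) or LLC replicate 3 (0.111). Of the cholesterol list, 4 of 23 genes rose. Among these, the sterol enzyme genes Sqle and Sc5d, at 0 in all LCMV libraries, were at least 14.1-fold and 13.9-fold higher in LLC (adjusted p 0.0365 each), and the sterol-regulated gene Tmem97, also at 0 there, at least 6.51-fold (adjusted p 0.0490). These 3 calls ended without LLC replicate 1 (0.0784 for Sqle and Sc5d and 0.0791 for Tmem97) or LLC replicate 3 (0.0827). That on Tmem97 ended also without LCMV replicate 1 (0.0644), LCMV replicate 2 (0.0698) or LCMV replicate 3 (0.0552).

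Of the mitochondrially encoded list, 3 of 13 genes rose in LLC over the list alone. These were the oxidative phosphorylation genes mt-Nd3 with 3.14 (SE 0.86, adjusted p 0.0394), mt-Atp8 with 3.08 (SE 0.97, adjusted p 0.0460) and mt-Co3 with 2.49 (SE 0.83, adjusted p 0.0460). Without LLC replicate 1 their log2 fold changes were 2.14, 1.27 and 1.39 and did not pass, at adjusted p of 0.392, 0.581 and 0.581. The calls on these 3 genes also ended without LCMV replicate 1, with adjusted p of 0.121 for mt-Nd3, 0.1598 for mt-Atp8 and 0.246 for mt-Co3. They ended without LCMV replicate 2 (0.205 for all 3) and without LCMV replicate 3 (0.0994 for mt-Nd3 and mt-Atp8 and 0.1002 for mt-Co3), and that on mt-Co3 ended without LLC replicate 3 (0.0518).

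The list of MDSC suppression genes was not called between LLC and LCMV, at a camera adjusted p of 0.491 and a median of 0.47, and its 1 gene that passed over the list alone was Cd274, which fell (adjusted p 0.0488). In that list the call on Cd274 ended without LLC replicate 1 (0.197), LLC replicate 3 (0.215), LCMV replicate 1 (0.0961), LCMV replicate 2 (0.0717) or LCMV replicate 3 (0.0632). Classical monocyte identity had an adjusted p of 0.697 and a median of 0.07, with Lyz2, the lysozyme gene, at -0.65 (SE 0.83). Non-classical monocyte identity had 0.117 and a median of -0.05, or -0.07 with genes at 0 in a group set at their bound, and a mean of 0.18. Other lists of white cells were not called, with adjusted p of 0.182 for progenitors, 0.260 for neutrophils and 0.720 for dendritic cells. For B cells it was 0.342, for plasma cells 0.845, for NK and cytotoxic cells 0.141, and for complement and Fc receptors 0.146. The neutrophil receptor gene Csf3r had 2.15 (SE 1.23). Erythroid markers had an adjusted p of 0.857 and markers of stroma, endothelium and carcinoma 0.419. Among pathways, adjusted p was 0.476 for replication-dependent histones, 0.907 for the unfolded protein response and 0.933 for hypoxia and glycolysis. It was 0.342 for nuclear-encoded oxidative phosphorylation, 0.720 for mitochondrially encoded genes and 0.845 for ribosomal proteins. It was 0.410 for the NF-kB response, 0.660 for immediate early and handling stress genes, 0.333 for cholesterol synthesis and uptake, 0.642 for fatty acid handling and 0.720 for autophagy and lysosome.

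The median of the NK and cytotoxic list was -1.04, and 0.00 with genes at 0 in a group set at their bound. With such bounds the oxidative phosphorylation median was 0.09 in place of 0.13 and that of fatty acid handling 0.05 in place of 0.06. Because the median of all genes was 0.61, camera gave a negative direction to the uncalled lists of MDSC suppression, classical monocytes, dendritic cells, B cells, stroma, oxidative phosphorylation, ribosomal proteins, NF-kB, immediate early and fatty acid genes, whose own medians were above 0. The unfolded protein response had a positive camera direction with a relative median of -0.16, and the complement list had a negative median of -0.13. Between scalings the relative medians of autophagy, cholesterol, hypoxia, plasma cell and histone genes changed sign, and none of these lists was called here. The megakaryocyte and platelet list kept 4 tested genes and the basophil, eosinophil and mast cell list kept 3, fewer than the 5 needed, and neither was tested.

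M-MDSC of tumour-bearing mice were next compared with those of naive mice, the untreated control. Cell division genes were higher in LLC. In the G2 and M phase list, all 41 tested genes had a higher estimate in LLC, although 0 passed over the list alone. Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361) was at 52.0 ± 30.3 CPM in LLC and 2.45 ± 0.0806 in naive, a log2 fold change of 4.40 (SE 1.82, adjusted p over the list alone 0.223). Top2a, the topoisomerase of dividing cells, was at 19.6 ± 9.70 CPM in LLC and 4.06 ± 0.511 in naive (log2 fold change 2.27, SE 1.23, adjusted p 0.245). In the S phase list, all 38 genes had a higher estimate and 0 passed over the list alone.

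The G2 and M median was 2.48, or 2.55 relative to all genes, with a camera adjusted p of 8.88e-33 and adjusted p = 0.203 with an estimated correlation. The S phase median was 1.96, or 2.02 relative to all genes, with a camera adjusted p of 2.72e-21 and adjusted p = 0.203 with an estimated correlation. Without LCMV replicate 1, which is in neither group but shares the estimate of spread, 25 of 41 G2 and M genes and 15 of 38 S phase genes rose adjusted over the list alone. In that fit the S phase list passed with adjusted p = 0.0179 with an estimated correlation, and the G2 and M list did not, with adjusted p = 0.0748. The list of replication-dependent histones, whose genes are near-identical, had 39 of 46 genes higher, 0 passing over the list alone, and a median of 0.98. It had a camera adjusted p of 8.67e-06 and adjusted p = 0.687 with an estimated correlation. By mean log2 CPM LLC replicate 2 lay below both naive libraries, at -0.24 against 0.28 and 0.57. The most abundant histone genes, the linker histones Hist1h1c at -0.50 (SE 0.89) and Hist1h1d at -0.85 (SE 0.93), had lower estimates and did not pass.

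Genes of myeloid progenitors and primary granules were higher in LLC than in naive, with 15 of 18 tested genes higher and 0 passing over the list alone. Mpo, the granule enzyme myeloperoxidase, had a log2 fold change of 5.96 (SE 2.43, adjusted p over the list alone 0.112), and Gfi1, a transcription factor of granulocyte progenitors, was at 0 in both naive libraries and at least 75.8-fold higher in LLC (adjusted p 0.112). The most abundant genes of the list were Cebpa, a myeloid transcription factor, at -1.85 (SE 0.91), and Igfbp4 at 0.11 (SE 0.92). The list median was 2.88, or 2.95 relative to all genes, with a camera adjusted p of 8.54e-11 and adjusted p = 0.203 with an estimated correlation. When LCMV replicate 1 was left out, the list had 7 genes that rose and 1 that fell, and did not pass with adjusted p = 0.122 with an estimated correlation. The neutrophil list had 16 of 21 genes higher, 0 passing, and a median of 0.45, with a camera adjusted p of 0.0374 and adjusted p = 0.716 with an estimated correlation. This call ended without LLC replicate 3 (0.288) or LCMV replicate 1 (0.0976). Its most abundant genes Csf3r at -0.05 (SE 1.32) and Cd177 at 0.11 (SE 1.40) did not pass. Erythroid markers were not called (adjusted p 0.475, median -0.15, mean 0.60). Their summed level was 19.7 CPM in LLC replicate 3 and 3.15 to 5.05 CPM in LLC replicates 1 and 2, against 3.27 and 3.89 CPM in naive.

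**Figure D2:**
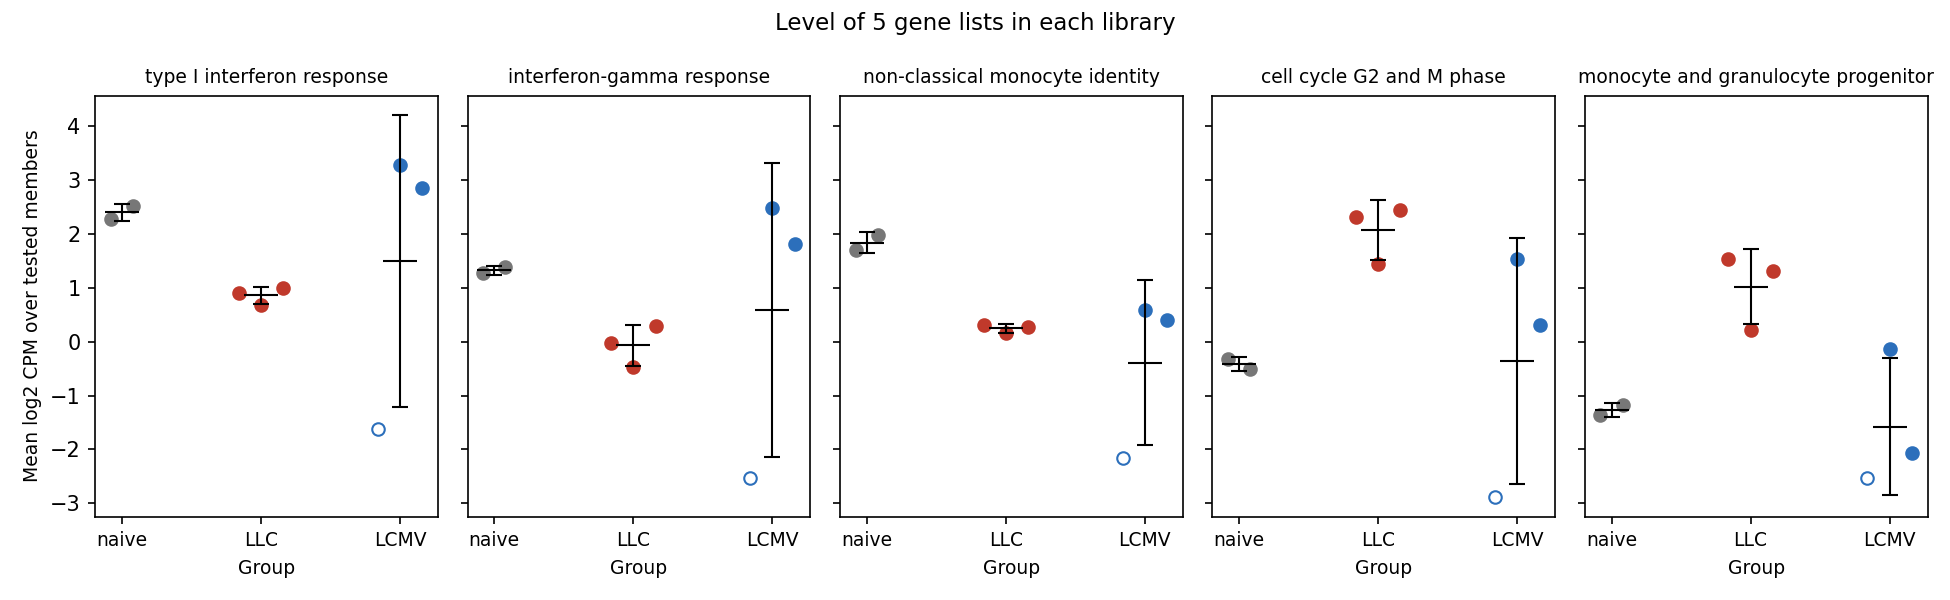
Each panel plots, for 1 gene list, the mean log2 CPM over its tested genes (y axis) in every library by group (x axis), with points for libraries, an open symbol for LCMV replicate 1, and lines with bars for the group mean ± SD. G2 and M genes lie at 1.44 to 2.45 in LLC and at -0.51 and -0.33 in naive, and type I interferon genes at 0.68 to 1.00 in LLC, 2.28 and 2.51 in naive, 2.84 and 3.28 in LCMV replicates 3 and 2, and -1.61 in LCMV replicate 1.

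Genes of mature, patrolling monocytes were lower in LLC than in naive. In the non-classical monocyte list, 20 of 22 genes had a lower estimate and 0 passed over the list alone. Nr4a1, the transcription factor this subset depends on, was at 27.9 ± 24.0 CPM in LLC and 73.1 ± 3.33 in naive (log2 fold change -1.39, SE 1.09), and Itgal, an integrin chain, had -0.31 (SE 1.17). The list median was -1.35, with a camera adjusted p of 2.06e-07 and adjusted p = 0.203 with an estimated correlation. Once LCMV replicate 1 was left out, the set passed with adjusted p = 0.0420 with an estimated correlation, and 3 genes fell adjusted over the list alone. Type I interferon genes were lower too, in 35 of 39 genes with 0 passing, a median of -1.56, a camera adjusted p of 1.19e-10 and adjusted p = 0.446 with an estimated correlation. Without LCMV replicate 1, 14 of these genes fell adjusted over the list alone, and the set passed with adjusted p = 0.0179 with an estimated correlation. Ifi204 was at 7.44 ± 1.63 CPM in LLC against 34.4 ± 3.09 in naive (log2 fold change -2.21, SE 0.77, adjusted p 0.320), and Parp14, an interferon-induced ADP-ribosyltransferase, had -0.37 (SE 0.84). The interferon-gamma list had 35 of 37 genes lower, 0 passing over the list alone, and a median of -1.37. It had a camera adjusted p of 4.36e-08 and adjusted p = 0.547 with an estimated correlation, and 5 genes fell without LCMV replicate 1, where the set did not pass with adjusted p = 0.0748 with an estimated correlation.

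The MHC class II list had 12 of 14 genes lower in LLC than in naive, 0 passing over the list alone, and a median of -1.64, with a camera adjusted p of 2.03e-04 and adjusted p = 0.547 with an estimated correlation. Cd74 was at 8.74 ± 9.41 CPM in LLC and 37.9 ± 2.05 in naive (log2 fold change -2.12, SE 1.15, adjusted p 0.288), and 6 genes fell without LCMV replicate 1. The red pulp macrophage list had 12 of 15 genes lower, 0 passing, and a median of -0.92, with a camera adjusted p of 1.02e-03 and adjusted p = 0.208 with an estimated correlation. Its call ended without naive replicate 2 (0.141). Adgre1 was at 5.10 ± 0.878 CPM in LLC and 9.65 ± 0.425 in naive, and 4 genes of this list fell without LCMV replicate 1. The list of stroma, endothelium and carcinoma markers had 4 of 6 genes lower and 2 that fell. The pericyte receptor gene Pdgfrb was at least 8.59-fold lower and the epithelial cadherin gene Cdh1 at least 5.02-fold lower, both at 0 in all 3 LLC libraries (adjusted p over the list alone 0.0358). Its median was -1.23, with a camera adjusted p of 0.0147 and adjusted p = 0.208 with an estimated correlation, and the call of the set ended without LLC replicate 3 (0.0557) or LCMV replicate 1 (0.0976). The calls on Pdgfrb and Cdh1 ended without naive replicate 3 (0.225), LLC replicate 1 (0.0728) or LLC replicate 3 (0.0517), and that on Pdgfrb also without naive replicate 2 (0.292). The list had 0 genes that fell without LCMV replicate 1.

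Mitochondrially encoded transcripts rose in LLC, in 13 of 13 genes adjusted over the list alone. The cytochrome oxidase gene mt-Co2 (mitochondrial genome, 7013 to 7696) was at 2415 ± 1058 CPM in LLC and 180 ± 16.8 in naive (log2 fold change 3.75, SE 0.87, adjusted p 0.0118), mt-Cytb had 3.17 (SE 0.91, adjusted p 0.0218), mt-Nd3 3.24 (SE 1.02, adjusted p 0.0218) and mt-Atp8 3.77 (SE 1.18, adjusted p 0.0218). The list median was 2.67, or 2.73 relative to all genes, with a camera adjusted p of 2.72e-21 and adjusted p = 0.203 with an estimated correlation. As a share of all counts the same transcripts were 3.18% ± 2.00 in LLC and 2.70% ± 2.54 in naive, so the difference is relative to the other coding genes. The call on mt-Co2 ended without naive replicate 2 (0.110), and those on mt-Cytb, mt-Nd3 and mt-Atp8 without naive replicate 2 (0.121) or LLC replicate 1 (0.0967), where they were 2.23, 2.24 and 1.95. Nuclear-encoded oxidative phosphorylation genes had 56 of 68 lower, 0 passing over the list alone, and a median of -0.59. They had a camera adjusted p of 1.02e-03 and adjusted p = 0.716 with an estimated correlation. Atp5l, an ATP synthase subunit, had -2.20 (SE 1.51) and Atp5a1 -0.23 (SE 1.45). Ribosomal protein genes were lower in 63 of 78 genes, 0 passing, with a median of -0.68, a camera adjusted p of 1.22e-04 and adjusted p = 0.716 with an estimated correlation, with Rps9 at -0.83 (SE 1.46) and Rps2 at 0.43 (SE 0.89). Without LLC replicate 3 the oxidative phosphorylation call (0.0557) and the ribosomal protein call (0.120) ended.

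Lists not called between LLC and naive had camera adjusted p from 0.0546 to 0.952. MHC class I was at 0.0546, with H2-D1, a classical class I gene, at 56.4 ± 15.9 CPM in LLC and 108 ± 0.760 in naive. Classical monocyte identity was at 0.0910, with Lyz2 at 81.5 ± 24.2 CPM in LLC and 412 ± 39.6 in naive (log2 fold change -2.34, SE 0.92, adjusted p over the list alone 0.588). The NK and cytotoxic list was at 0.0791 with a median of -1.58, or -0.88 with bounds, and 2 of its 6 genes fell. These were the NK receptor genes Klrd1, at least 5.63-fold lower, and Klre1, at least 4.13-fold lower, both at 0 in all 3 LLC libraries (adjusted p 0.0386). Both calls ended without LLC replicate 1 (0.0828) or LLC replicate 3 (0.0690). That on Klrd1 ended also without naive replicate 2 (0.242) and that on Klre1 without naive replicate 3 (0.224), and 0 genes of the list fell without LCMV replicate 1. MDSC suppression genes were at 0.211, with the transcription factor gene Cebpb at -2.02 (SE 1.08), and T cell markers at 0.584. Fatty acid genes had a median of -0.02, which was 0.04 relative to all genes and changed sign between scalings, and autophagy genes had a negative median of -0.13 with a positive camera direction.

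The last comparison asked how M-MDSC of infected mice differ from those of naive mice. LCMV replicate 1, with its 2731 coding genes, lowered many estimates in this group. By mean log2 CPM it lay below both naive libraries in the G2 and M, S phase, type I interferon, interferon-gamma and MHC class I lists, where LCMV replicates 2 and 3 lay above both. Mitosis genes were higher in LCMV, with 34 of 41 G2 and M genes higher and 0 passing over the list alone, and Mki67 at 21.7 ± 19.6 CPM in LCMV and 2.45 ± 0.0806 in naive (log2 fold change 3.14, SE 1.70). The median was 1.38, or 2.05 relative to all genes. Camera returned an adjusted p of 8.27e-09 and adjusted p = 0.985 with an estimated correlation, and 8 genes rose without LCMV replicate 1. S phase genes were higher in 25 of 38, 0 passing, with a median of 0.84, a camera adjusted p of 2.28e-03 and adjusted p = 0.985 with an estimated correlation. The S phase call ended without LCMV replicate 2 (0.0730). The S phase genes E2f2, a cell cycle transcription factor, and Pole, a DNA polymerase subunit, had -0.35 (SE 0.89) and 0.83 (SE 1.15), and without LCMV replicate 1, 5 S phase genes rose and 1 fell.

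Interferon lists were higher in LCMV than in naive relative to all genes. Of the type I list 24 of 39 genes were higher and 0 passed over the list alone. It had a median of 0.44, or 1.11 relative to all genes, a camera adjusted p of 2.52e-03 and adjusted p = 0.985 with an estimated correlation. Parp14 was at 81.7 ± 51.1 CPM in LCMV and 33.5 ± 4.74 in naive (log2 fold change 1.29, SE 0.89), and Ifi204 had 0.64 (SE 0.79). Of the interferon-gamma list 18 of 37 genes were higher, 0 passed, and the median was -0.05 where the mean was 0.71 and the relative median 0.61. It had a camera adjusted p of 2.52e-03 and adjusted p = 0.985 with an estimated correlation. Cd274 had a log2 fold change of 3.39 (SE 1.30, adjusted p over the list alone 0.268), and without LCMV replicate 1 it was 2.42. MHC class I genes were higher in 12 of 16, 0 passing, with a median of 0.20, or 0.86 relative to all genes, a camera adjusted p of 0.0310 and adjusted p = 0.985 with an estimated correlation. Among them H2-K1 had 0.15 (SE 0.80) and H2-D1 -0.92 (SE 0.96). Without LCMV replicate 2 the type I (0.0730), interferon-gamma (0.182) and class I (0.204) calls ended. Without LCMV replicate 1, 0 type I, 4 interferon-gamma and 1 class I genes rose adjusted over the list alone.

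Camera ranked the progenitor list higher in LCMV relative to all genes, with 11 of 18 genes higher, 0 that rose over the list alone and 1 that fell. That gene was Flt3, at least 55.0-fold lower in LCMV (adjusted p 0.0142), and its call ended without naive replicate 2 (0.0556) or naive replicate 3 (0.0584). By mean log2 CPM only LCMV replicate 2 (-0.14) lay above naive (-1.36 and -1.18), and LCMV replicates 1 and 3 lay below, at -2.53 and -2.07. The list median was 1.69, or 2.35 relative to all genes, where the mean was 0.65 and the median under quality weights 0.35, with a camera adjusted p of 7.47e-03 and adjusted p = 0.802 with an estimated correlation, and the call ended without LCMV replicate 1 (0.0731) or LCMV replicate 2 (0.182). Mitochondrially encoded genes were higher in 13 of 13, and 1 rose over the list alone, mt-Nd6, at 2979 ± 958 CPM in LCMV and 226 ± 47.4 in naive (log2 fold change 3.72, SE 1.04, adjusted p 0.0464). The median was 1.39, or 2.06 relative to all genes, with a camera adjusted p of 8.15e-11 and adjusted p = 0.802 with an estimated correlation, while the share of all counts was 1.32% ± 0.546 in LCMV and 2.70% ± 2.54 in naive. The call on mt-Nd6 ended without naive replicate 2 (0.271), naive replicate 3 (0.0708), LCMV replicate 1 (0.129), LCMV replicate 2 (0.0568) or LCMV replicate 3 (0.0835).

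Sterol genes were lower in LCMV than in naive, with 19 of 23 lower and 3 that fell. Among these, Sc5d was at least 44.7-fold and Sqle at least 33.5-fold lower, both at 0 in all 3 LCMV libraries (adjusted p over the list alone 0.0202 each). These 2 calls held without LCMV replicate 1 and ended without naive replicate 2 (0.0689) or naive replicate 3 (0.0943). The cholesterol list had a median of -1.32, or -0.66 relative to all genes, with a camera adjusted p of 0.0438 and adjusted p = 0.985 with an estimated correlation. It was lost without any 1 library of the 2 groups, at 0.0574 and 0.0771 without naive replicates 2 and 3 and at 0.0731, 0.0606 and 0.202 without LCMV replicates 1, 2 and 3. Ribosomal protein genes were lower in 70 of 78, 0 passing, with a median of -1.22, or -0.55 relative to all genes, a camera adjusted p of 0.0464 and adjusted p = 0.985 with an estimated correlation. Their call ended without naive replicate 2 (0.238), naive replicate 3 (0.196) or LCMV replicate 3 (0.748). Mrc1, the mannose receptor of tissue macrophages, fell as 1 of 15 red pulp macrophage genes, at 2.26 ± 0.359 CPM in naive and 0 in LCMV, at least 45.2-fold lower (adjusted p 0.0224). Its call ended without naive replicate 2 (0.0913) or naive replicate 3 (0.118). T cell markers were not called, at an adjusted p of 0.0994 and a median of 0.94, and B cell markers were at 0.118, with Ms4a1, which encodes CD20, at 7.71 ± 2.06 CPM in LCMV and 3.58 ± 2.07 in naive.

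Lists not called between LCMV and naive had camera adjusted p from 0.0994 to 0.955, the highest for the MDSC suppression, neutrophil and red pulp macrophage lists. The median of all genes was -0.66 here, and camera gave a positive direction to several uncalled lists with negative medians, among them MDSC suppression at -0.62, neutrophil at -0.15, NF-kB at -0.60 and complement at -0.50. Median and mean differed in sign for B cell genes (0.47 and -0.16), plasma cell genes (0.17 and -0.03) and histones (0.04 and -0.30). The hypoxia median was -0.63, or -0.53 with genes at 0 in a group set at their bound. Between scalings the relative medians of the MDSC suppression and red pulp macrophage lists changed sign.

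The 25 genes fixed in advance held the effector and identity genes of MDSC. Arg1, Nos2 and Il10, which encode arginase, inducible nitric oxide synthase and an inhibitory cytokine, and the lipid transporter gene Slc27a2 had 0 counts in all 8 libraries, which allows up to 0.0153 CPM in naive, 0.0346 in LLC and 0.0499 in LCMV for 3 counts over the group. The neutrophil marker Ly6g had 44 counts in all and was not tested. Monocyte genes were present in each group, with the chemokine receptor gene Ccr2 at 109 ± 13.0 CPM in naive, 31.2 ± 11.5 in LLC and 29.8 ± 35.6 in LCMV. Csf1r, the receptor of a monocyte growth factor, was at 64.8 ± 1.52, 34.6 ± 7.25 and 27.9 ± 22.3, and Itgam, which encodes CD11b, at 33.4 ± 0.681, 43.6 ± 2.88 and 30.0 ± 14.1. Ly6c2, the sorting marker of monocytic cells, was at 14.8 ± 0.0276 CPM in naive, 8.36 ± 7.20 in LLC and 21.6 ± 34.1 in LCMV, and its log2 fold change between LLC and LCMV was -1.37, and 2.09 without LCMV replicate 2. The alarmin gene S100a8 was at 1.25 ± 0.149, 5.74 ± 4.27 and 3.46 ± 3.15 CPM. Of the 20 fixed genes tested, Cd274 alone passed in edgeR adjusted over the list alone, in LLC against LCMV (0.0337), and among the rest the lowest adjusted p there was 0.0519, for Isg15, Cxcl9 and the stress gene Ddit3. Ddit3 was at 0 in all LCMV libraries and at least 7.97-fold higher in LLC.

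Both comparisons with naive share its 2 libraries, so chance alone gives them genes in common. In edgeR, 0 genes were called in either. At an unadjusted p under 0.05, 143 genes moved the same way in LLC and LCMV and 4 moved in opposite directions. Simulated unchanged groups that share the naive libraries gave 208 genes on average and 241 at most in the same direction over 20 simulations, and independence would give 18.7. Across genes, which are not independent replicates, the correlation of the fold changes was 0.301 where the simulations gave 0.589, and the covariance was 1.03 where they gave 1.66. The simulations gave all libraries the same spread for a gene, estimated over the 3 groups together. The real naive libraries correlated at 0.904 with each other, and LCMV replicate 1 at only 0.344 to 0.468 with the other libraries. The simulated noise from the shared naive libraries may therefore be too large, and the simulations cannot tell whether the sharing was above or below chance.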

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

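The tests of LCMV replicate 1 as the only cause, of T cell RNA by its excess, of erythroid RNA by its excess and of progenitors were chosen only after the result was seen. First versions of the T cell and erythroid tests, written earlier, asked only whether summed markers were above both naive libraries, and T cell markers were, in 2 of 2 LCMV libraries with raised interferon genes, as that explanation needs. Erythroid markers were in LLC replicates 1 and 3, while LLC replicate 2 lay below both naive libraries over the 5 tested members (3.15 CPM against 3.27 and 3.89) and barely above over all 25 members (3.95 against 3.44 and 3.93), so that version does not decide.

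Against naive, 5 lists had opposite camera directions in LLC and in LCMV, and their difference, tested as LLC against LCMV, passed. These were the type I interferon list (adjusted p 8.08e-15, and adjusted p = 0.840 with an estimated correlation), the interferon-gamma list (4.86e-12, and adjusted p = 0.840 with an estimated correlation), the MHC class I list (1.84e-04, and adjusted p = 0.887 with an estimated correlation), the T cell list (0.0390, and adjusted p = 0.840 with an estimated correlation) and the red pulp macrophage list (0.0479, and adjusted p = 0.840 with an estimated correlation). The relative median of red pulp macrophage genes in LCMV against naive was 0.11 and changed sign between scalings. The T cell call ended without LLC replicate 2 (0.0921) or LCMV replicates 1, 2 or 3 (0.136, 0.326 and 0.265), and the macrophage call without LLC replicates 1 or 3 (0.0989 and 0.106) or LCMV replicates 2 or 3 (0.0503 and 0.110).

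The interferon lists were lower in LLC than in LCMV, where type I genes summed to 608 and 726 CPM in LCMV replicates 2 and 3, 211 CPM in LCMV replicate 1, 335 and 385 CPM in naive and 181 to 185 CPM in LLC libraries. LCMV replicate 1 lay below LCMV replicates 2 and 3, by summed CPM and by mean log2 CPM (-1.61 against 3.28 and 2.84). It therefore lowered the LCMV level and was not what raised it. Leaving it out was bound to keep the difference in level, so the call without it is no separate test (camera adjusted p 7.19e-34, and adjusted p = 0.00538 with an estimated correlation). Unequal depth on nuclear coding genes is argued against, as the cause of the difference in level, by thinning. With all libraries at 318731 coding counts, the type I median relative to all genes was -2.26 (median over 20 draws), against -2.36 in the full data. The highest camera adjusted p over the 20 draws was 1.30e-13 at the preset correlation. Thinning did not even out the coding genes detected, which were 2730 to 9115 in LCMV and 10098 to 11156 in LLC and naive libraries. With an estimated correlation the call on the full data was lost (adjusted p = 0.840). T cell RNA could account for little of the part above naive unless its cells hold few marker transcripts for their interferon transcripts, a ratio not measured here, as its excess was at most 0.446% of the interferon excess in the 2 LCMV libraries above both naive libraries, where summed T cell markers were 7.02 and 7.38 CPM against 2.26 and 6.03 CPM in naive. That test does not bear on the LLC libraries, which were themselves below naive. A response to infection, a loss of interferon signalling in tumour-bearing mice, or both remain open as untested biological explanations, and the labels cannot part them from the different days.

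Cell cycle lists were higher in LLC than in naive, with summed G2 and M genes at 327, 187 and 345 CPM in LLC replicates 1 to 3 against 59.7 and 53.4 CPM in naive. Unequal depth is argued against by thinning, where the G2 and M median relative to all genes was 2.50 (median over 20 draws), against 2.55 in the full data. The highest camera adjusted p of that list over the 20 draws was 3.82e-27 at the preset correlation, where the full data gave 8.88e-33 (and adjusted p = 0.203 with an estimated correlation). Erythroid progenitor RNA is argued against as the whole cause by the low level of its markers, with Klf1, Gata1, Epor and Car1 at no more than 0.0572 CPM in any LLC library and an erythroid excess of at most 5.71% of the G2 and M excess, in LLC replicate 3, where the transferrin receptor gene Tfrc was at 17.4 CPM, although the ratio of these markers to division genes in such cells was not measured. Monocyte and granulocyte progenitors among the sorted cells are left open, because the progenitor list, which shares 0 genes with the cell cycle lists, was itself higher in LLC (camera adjusted p 8.54e-11, and adjusted p = 0.203 with an estimated correlation) but does not tell which cells held the division genes, and its excess was 23.8%, 5.43% and 12.6% of the G2 and M excess in LLC replicates 1 to 3. Division of the M-MDSC themselves in tumour-bearing mice was not tested apart from it.

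LCMV replicate 1 detected 2731 nuclear protein-coding genes. Lower depth is argued against, since LCMV replicates 2 and 3 thinned to the same coding depth still detected 9115 and 9017 genes, a ratio to replicate 1 of at least 3.30. Few RNA molecules amplified into many reads may account for it, as 7.88% of its detected coding genes had 1 to 3 counts. Thinned to its depth, LCMV replicates 2 and 3 had 14.5% and 15.9%, and the LLC and naive libraries 20.5% to 23.4%. The low share was thus most marked in replicate 1 but held for the whole LCMV group, where it cannot be told apart from infection. The labels give no difference between this library and the others of its group, and no biological explanation was tested.

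The 6 LLC and LCMV libraries allow 10 splits into 3 and 3, too few for a share under 0.05. For genes called by edgeR the real split gave 0 and the highest other split 1, and all 10 splits gave as many as the real one. For lists called by camera the real split gave 8 and the highest other split 14, and 5 of the 10 splits gave as many. The type I interferon list, at 8.08e-15 in the real split (and adjusted p = 0.840 with an estimated correlation), had an adjusted p of 9.77e-12, 7.72e-10 and 5.41e-11 in the 3 other splits that keep LCMV replicates 2 and 3 together, and 0.0732 to 0.505 in the rest, so groups that mix LLC and LCMV libraries also call it.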

How the results depend on the processing

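With DESeq2 size factors, total library size, the stricter filter, abundant genes removed (not Gm26917 or Gm42418) or a 2-fold threshold, edgeR called 0 genes in all 3 comparisons, as it did without any 1 library of the groups compared (range 0 to 0), so these settings cannot show stability. Counts for LLC against LCMV, LLC against naive and LCMV against naive in this order were 33, 19 and 32 with every gene of at least 1 count, 841, 19 and 413 with DESeq2, and 0, 1 and 31 with limma-voom. With only the samples of the 2 groups they were 0, 104 and 673. Of the alternatives chosen after seeing the data, limma-voom with quality weights gave 176, 927 and 25, limma-voom without LCMV replicate 1 gave 320, 27 and 577, and DESeq2 without it gave 1168, 311 and 855. With the replicate number as a block edgeR called 1, 1 and 2 genes and limma-voom 0, 0 and 0. Same-number libraries of different groups correlated at -0.0376 to 0.124 in their deviations from group means, and those with different numbers at -0.124 to 0.0945. The deviations of the 2 naive libraries mirror each other, so their values are not separate. No clear pairs were visible, but the check is weak and cannot exclude pairing. The cause of the differences in gene counts between settings was not tested. The overlap of genes called against naive was 0 in edgeR, 9 with DESeq2, 1 with the block, 9 with every gene of at least 1 count, and 0 to 0 without single libraries.

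For lists, camera called 8, 14 and 9. An estimated correlation and fry each left 0, 0 and 0, and without LCMV replicate 1 an estimated correlation left 2, 3 and 0. With the block the counts were 3, 15 and 9. Without single libraries they ranged from 4 to 11, 10 to 15 and 4 to 10. For LLC against LCMV they were 4 without LLC replicate 1, 5 without LLC replicate 3 and 5 without LCMV replicate 3, and for LCMV against naive 4 without LCMV replicate 2. Of the 31 calls, DESeq2 size factors kept all 31, the block 26, every gene of at least 1 count 28, camera on weighted values 27 and leaving out LCMV replicate 1 26, while an estimated correlation kept 0 (adjusted p 0.203 to 0.985). With fry the direction reversed for MHC class II (0.985) and red pulp macrophage genes (0.8997) in LLC against LCMV, and for type I interferon (0.929), interferon-gamma (0.929), MHC class I (0.934), progenitor (0.985) and S phase genes (0.929) in LCMV against naive. Fry does not compare with other genes, whose median was 0.61 and -0.66 there, and by construction its directions are not relative to them. For named genes, 747 values under alternatives kept direction and side of the threshold, 166 lost the call, 20 gained it and 41 changed direction. The 747 include fixed genes that passed neither in the main fit nor in the alternative, so they do not measure how stable the calls were. The upper-quartile alternative was not run, because the upper quartile of tested genes was 0 in LCMV replicate 1. In simulated data with this spread edgeR found 6% of 16-fold changes, against 100% with a dispersion of 0.1, so the spread between libraries limits what can be called. There DESeq2 called 0.674% of 14118 unchanged genes, so part of its higher gene counts may be false.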

Other observations

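When libraries were weighted by quality, a setting chosen after seeing the data, limma-voom called 448 genes higher and 479 lower in LLC than in naive. Adjusted over all genes, 10 of 18 progenitor genes rose and 1 fell, 32 of 41 G2 and M genes and 20 of 38 S phase genes rose, and 8 of 14 MHC class II genes and 9 of 22 non-classical monocyte genes fell. Among the called genes with large changes and groups that do not overlap, Mpo, myeloperoxidase, had a log2 fold change of 5.93 (SE 0.76, adjusted p 8.08e-04), Prtn3 and Elane, serine proteases of the same granules, had 4.75 (SE 0.64, adjusted p 1.10e-03) and 4.86 (SE 0.89, adjusted p 6.02e-03), and Uhrf1, which maintains DNA methylation in S phase, had 5.28 (SE 0.61, adjusted p 6.37e-04). Abca13, a transporter gene, had 5.47, and Cit, a kinase gene of cell division, 5.59. Among genes lower in LLC were Cx3cr1, the fractalkine receptor of patrolling monocytes, at -3.38 (SE 0.48, adjusted p 1.38e-03), the class II genes H2-Ab1, Cd74 and H2-Aa at -3.41, -3.25 and -3.18, the chemokine gene Ccl6 at -2.92, the prostaglandin-degrading enzyme gene Hpgd at -4.54 and the transferrin gene Trf at -3.47. Of the 927 genes, 26 also passed in limma-voom without LCMV replicate 1, which changed both the weights and the libraries. The log2 fold changes of Mpo, Prtn3, Elane and Cx3cr1 stayed of similar size there, at 5.77, 4.57, 4.71 and -3.04. None of these passed (adjusted p 0.169, 0.123, 0.280 and 0.0906). Nor did Abca13 (0.0838), Cit (0.0718), H2-Ab1 (0.0747), Cd74 (0.159), H2-Aa (0.121), Ccl6 (0.0718), Trf (0.0701) or Hpgd (0.103), whose log2 fold change moved to -5.45. Uhrf1 passed at 5.21 (adjusted p 0.0491). Mpo was at 30.8, 8.70 and 12.7 CPM in LLC replicates 1 to 3, 0.285 and 0.267 CPM in naive, and 12.3 CPM in LCMV replicate 2 with 0 in LCMV replicates 1 and 3.

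Under the same weights, 176 genes were called between LLC and LCMV, 175 of them higher in LCMV, and 108 also passed in limma-voom without LCMV replicate 1. The balance of directions depended on the fit, since limma-voom without that library called 195 genes higher and 125 lower in LLC, DESeq2 619 and 222, and DESeq2 without that library 830 and 338. The weighted calls held 8 of 39 type I and 5 of 37 interferon-gamma genes. Rhox8, a homeobox gene of the reproductive tract on chromosome X from 37874778 to 37878944, was at 709 ± 588 CPM in LCMV, 17.1 ± 17.3 in LLC and 11.7 ± 5.56 in naive (log2 fold change against LCMV -6.27, SE 0.83, adjusted p 4.89e-03). It was at 1381 CPM in LCMV replicate 1 and at 296 and 448 CPM in LCMV replicates 2 and 3, and without LCMV replicate 1 limma-voom gave -5.56 (adjusted p 0.0232). LCMV replicates 1, 2 and 3 had quality weights of 0.0712, 0.456 and 0.946, and the other libraries 0.927 to 2.84.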
